A study of Danio rerio with 27 samples.

How the data were processed

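The data are 27 RNA libraries of adult zebrafish, each made from 30 sorted cells, in 4 groups given by the labels: sibling and spic mutant cells of epidermis (7 and 7) and of gill (5 and 8). The labels do not say whether libraries of a group came from separate fish, so p-values measure the spread between these libraries, part of which may be technical. The full genotype of the siblings is not given in the sources used here.

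The authors deposited 1 table of 32520 genes in TPM, with 1 column per library and no pooling. The submitters' processing notes name STAR, featureCounts and DESeq2, without versions, and the builds GRCz11 and danRer11; the role of each, the annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Paralogues and overlapping genes, such as those with nearly identical copies, are therefore uncertain to the extent that their reads could be split or lost. TPM values divide by gene length and rescale each library to a fixed sum, so that a gene's value also depends on all other genes. Gene symbols were used as the table gives them; 29201 identifiers were found in the reference table of gene names, and 10352 symbols were Ensembl identifiers. No coordinates are given, because the reference tables at hand name another assembly than the submitters' notes.

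TPM keeps no depth. The smallest step between low values was shared across libraries for 13274 genes, and from it the relative value of 1 read was estimated; counts were not recovered, so no count model was used. The spread of a library after 23 PCR cycles may exceed the counting error that these steps describe, which was not analysed here.

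Genes with at least 1 TPM in at least 5 libraries were tested, 13465 in all. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(TPM + 1), with 1 mean per group, all 27 libraries in 1 fit and 23 residual degrees of freedom; p-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Sharing 1 estimate of the spread assumes that the groups vary alike. Contrasts were mutant against sibling in each tissue, their difference, and gill against epidermis in each genotype. Fold changes are on the log2(TPM + 1) scale. The targeted gene was tested with an exact permutation test within each tissue. Gene lists, 30 with at least 5 tested members, were fixed before the data were examined and cover immune and other cell types, pathways and cell machinery; they were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. Camera compares a list with all other genes, while fry asks whether its genes move, on balance, one way.

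The rule for named genes was fixed before the data were examined: for each mutant contrast the 10 genes with the largest change in each direction past the threshold, with a mean of at least 10 TPM in 1 of the groups, and for other contrasts 5 per direction, leaving out clone-style names; where fewer passed, the genes with the smallest p filled the direction. Beside these came spic, mpeg1.1 and mpeg1.2, and up to 4 members with the smallest p per list and contrast. The gene epcam, the clone-named genes of the interaction and the genes that the closing section says so of were chosen after their values were seen. In epidermis, 1 gene that the rule selects is not reported here.

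The procedure was tested on simulated data with 200 changed genes among the 13465. The changed genes were drawn from genes well above the floor in siblings, so the recovery and the share of false calls hold for that setting. At a log2 change of 4, limma recovered 53.0% of the changed genes in the epidermal comparison and 48.9% in the gill comparison, and at a log2 change of 2, 9.60% and 9.00%; 3.62% of the calls in epidermis and 16.8% in gill were false. Lists drawn at random were called in 10% of draws for epidermis and 5% for gill. In that setting, changes of 2 were therefore mostly not detected. Falls that would pass the floor were cut there, so some were smaller than stated. More genes passed in the real data, which eases the threshold, so the recovery need not carry over.

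Alternatives fixed before the data were examined were other pseudocounts (0.1 and 10), no filter and a stricter filter (5 TPM in 10 libraries), quantile normalization, median centring, array weights, a fit of the libraries of a contrast alone, the number of detected genes as a covariate, the replicate number as a block, robust eBayes, a rank test, a minimum fold change and leaving out each library in turn. Added after the data were seen were leaving out mitochondrial features, setting values under 1% of a gene's highest library to 0, leaving out the 3 libraries with the fewest genes at 1 TPM, a ribosomal list without kinases, and leave-one-out fits for lists and for the means and calls of genes whose values are printed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sample-level reads were not analysed here.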

Results

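Transcripts were measured in metaphocyte progenitors of adult zebrafish, in fish mutant for spic and in their siblings. Metaphocytes are myeloid-like cells of zebrafish barrier tissues that arise outside the blood lineage, and spic encodes an Ets-family transcription factor. Each of the 27 libraries held 30 cells sorted as positive for a spic:EGFP reporter and negative for an mpeg1:DsRedx reporter, prepared by the Smart-seq2 method with 23 PCR cycles. Epidermis gave 7 sibling and 7 mutant libraries, and gill gave 5 sibling and 8 mutant libraries. The table gives TPM values, which keep no depth. From the smallest steps between values of low genes, 1 read was worth a median of 0.111 to 0.238 TPM, a 2.15-fold range between libraries, and 93.2% of low values came out whole within 0.05 of a step. The number of genes at 1 TPM or more was 8631 ± 511 (SD, n = 7) in sibling epidermis, 7534 ± 814 (SD, n = 7) in mutant epidermis, 9264 ± 860 (SD, n = 5) in sibling gill and 8937 ± 1126 (SD, n = 8) in mutant gill. Within a group, the median correlation between libraries across genes was 0.697 in sibling epidermis, 0.537 in mutant epidermis, 0.638 in sibling gill and 0.544 in mutant gill.

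The targeted gene was read first, although its level alone cannot check the genotype labels, since some untargeted genes fell further. In mutant epidermis 0.998% of the sibling mean was left for spi1a and 0.799% for ncf1, less than for spic. In epidermis, spic (ENSDARG00000012435) stood at 638 ± 76.3 TPM (SD, n = 7) in siblings and at 38.9 ± 40.5 TPM (SD, n = 7) in mutants. In gill it stood at 293 ± 132 TPM (SD, n = 5) in siblings and at 18.8 ± 17.7 TPM (SD, n = 8) in mutants. The mutant libraries reached 125 TPM at most in epidermis and 53.3 TPM in gill, below the lowest sibling library of each tissue at 561 and 140 TPM. The mean log2(TPM + 1) fell by 4.55 in epidermis (two-sided exact permutation test, p = 0.000583) and by 4.28 in gill (p = 0.000777), the smallest p that each set of regroupings can give. In mutants, 6.10% of the sibling mean was left in epidermis and 6.42% in gill; without mutant epidermis 5, the highest library, 3.85% was left in epidermis. The macrophage gene mpeg1.1 (ENSDARG00000055290), whose promoter drove the reporter that the sort excluded, stood at 210 ± 76.3 TPM in sibling epidermis, 1.29 ± 0.492 TPM in mutant epidermis, 103 ± 52.3 TPM in sibling gill and 1.71 ± 1.11 TPM in mutant gill. Its paralogue mpeg1.2 was above 1 TPM in 1 library, of mutant gill.

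**Figure D1:**
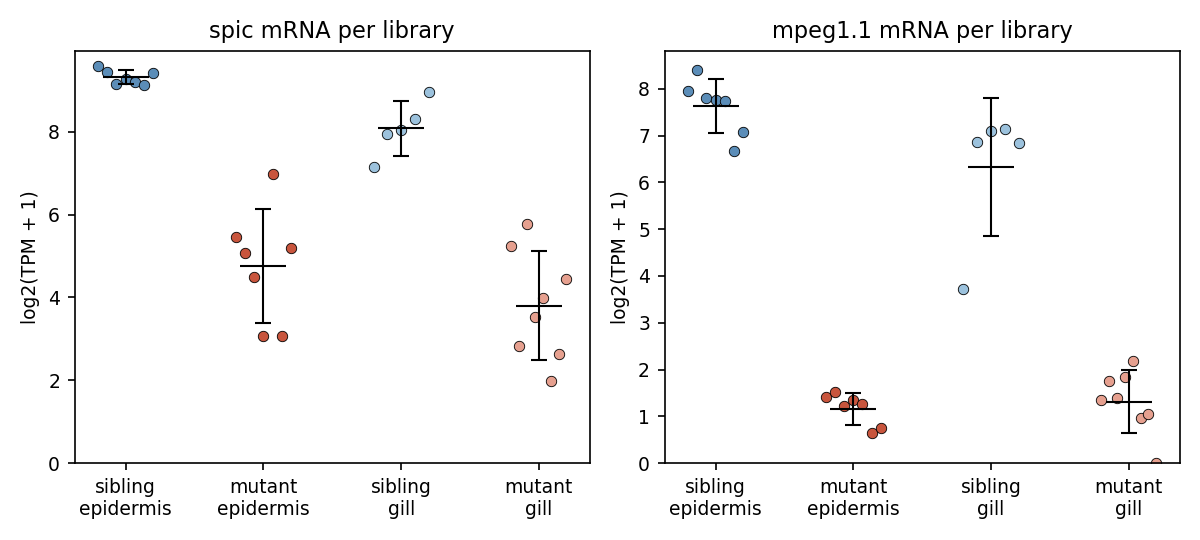
Levels of spic and mpeg1.1 in each library as log2(TPM + 1) on the vertical axis, by group on the horizontal axis; points are libraries (7 sibling epidermis, 7 mutant epidermis, 5 sibling gill, 8 mutant gill), and bars give the mean and SD. The highest mutant library for spic, at 125 TPM, lies below the lowest sibling library, at 140 TPM.

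The first comparison asked what differed between mutant and sibling cells sorted from the epidermis. Genes of the myeloid programme were lower in mutants and genes of neuroendocrine and sensory cells were higher. The myeloid transcription factor gene spi1a fell from 497 ± 106 to 4.95 ± 1.70 TPM (SD, n = 7 each). Its paralogue spi1b stood at 0 TPM in every sibling library of both tissues. It reached 1 TPM in 1 library only, mutant gill 6, at 74.0 TPM. The gene ncf1, a subunit of the phagocyte NADPH oxidase, fell from 1164 ± 447 to 9.30 ± 3.50 TPM. The chemokine receptor gene cxcr4b fell from 6136 ± 1764 to 335 ± 162 TPM. In the other direction, scgn, a calcium-binding protein of neuroendocrine cells, rose from 29.5 ± 39.2 to 2771 ± 1428 TPM. The secretory granule gene chga rose from 2.99 ± 4.17 to 427 ± 260 TPM and the transcription factor gene sox2 from 2.09 ± 1.81 to 299 ± 124 TPM. Without sibling epidermis 1 the sibling means of scgn and chga were 15.13 and 1.43 TPM. The epithelial adhesion gene epcam stood at 2592 ± 892 TPM in siblings and 1875 ± 1043 TPM in mutants, both SD of n = 7, and did not pass (limma, adjusted p = 0.292). It was chosen after its values were seen.

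Of 13465 genes tested in epidermis, 1726 passed an adjusted p of 0.05 in limma, 556 higher and 1170 lower in mutants, so that 32.2% were higher. The median log2 change over all tested genes was -0.27, and the balance of directions followed the scaling: quantile normalization gave 889 higher and 1006 lower genes, and median centring gave 834 higher and 718 lower. The 10 highest named genes rose by 6.38 to 6.82 on the log2(TPM + 1) scale, which understates changes of low genes. Besides those above, they were fxyd6, rgs5a, kitlgb, camk2n1a, insm1b, yjefn3 and crip3. Of these, rgs5a, a regulator of G-protein signalling, stood at 31.5 ± 45.1 TPM in siblings (15.21 TPM without sibling epidermis 1) and 2765 ± 1569 TPM in mutants. Of the lowest named genes, 9 had log2 changes of -6.86 to -6.47 and were crfb15, ncf1, il22ra2, spink4, pigrl4.2, mmp9, elovl5, cdh28 and mpeg1.1. All of these passed limma at an adjusted p of 1.71e-05 or lower.

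Of 30 gene lists fixed before the data were examined, 11 passed camera in epidermis with its preset correlation, and 5 of these held with an estimated correlation. In the myeloid list, 17 of 29 tested members fell and 1 rose (21 and 2 adjusted over the list alone), with a median log2 change of -3.70 and an adjusted p of 0.00178 with an estimated correlation. In the leukocyte cytoskeleton list, 18 of 22 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -4.15 and an adjusted p of 0.00101 with an estimated correlation. Its members included wasa, which fell from 322 ± 92.4 to 3.62 ± 1.35 TPM, and tmsb4x, which encodes an actin-binding thymosin and fell from 14458 ± 1735 to 2187 ± 684 TPM. In the neuroendocrine and sensory list, 14 of 27 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 2.82 and an adjusted p of 0.00374 with an estimated correlation. Its members atoh1a, a transcription factor gene of sensory cell fate, rose from 8.48 ± 13.5 (3.403 TPM without sibling epidermis 1) to 495 ± 300 TPM, and ddc, which encodes the enzyme that makes serotonin and dopamine from their precursors, from 0.661 ± 0.484 to 147 ± 106 TPM. The neutrophil list had 3 of 7 members lower, ncf1, mmp9 and pnp5a, of which ncf1 is also in the myeloid list (4 adjusted over the list alone; adjusted p = 0.0304 with an estimated correlation). The Notch list had 7 of 23 members higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.0467 with an estimated correlation). Its ligand gene dll4 rose from 0.621 ± 1.13 (0.195 TPM without sibling epidermis 1) to 67.5 ± 50.6 TPM, while mfng, a glycosyltransferase that modifies Notch receptors, fell from 92.9 ± 47.3 to 0.551 ± 0.617 TPM.

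The other 6 lists called in epidermis lost the call with an estimated correlation. Of 89 tested ribosomal protein genes 67 fell and 0 rose (77 lower adjusted over the list alone), with a median of -1.38, or -1.11 relative to all genes, and an adjusted p of 0.0932 with an estimated correlation. Median centring left 30 of them lower and quantile normalization 55. The list's pattern had also matched 9 rps6k kinase genes, and without them 66 of 80 fell. As a share of all TPM, ribosomal protein genes made up 9.24 ± 1.01% in siblings and 3.98 ± 1.41% in mutants (SD, n = 7 each). Of 54 immediate-early and stress genes 18 rose and 3 fell (25 and 6 adjusted over the list alone; adjusted p = 0.0638 with an estimated correlation), among them fosab, from 296 ± 156 to 3304 ± 1273 TPM, and socs3a, a feedback inhibitor of cytokine signalling, from 45.3 ± 23.9 to 1280 ± 775 TPM. Of 72 cell cycle genes 5 rose and 0 fell (2 higher adjusted over the list alone), with an adjusted p of 0.0932 with an estimated correlation; median centring gave 12 higher and quantile normalization 13. Of 15 MHC class II genes 9 fell and 0 rose (9 lower and 2 higher adjusted over the list alone; adjusted p = 0.0606 with an estimated correlation), including the invariant chain genes cd74a, from 4540 ± 675 to 1581 ± 1015 TPM, and cd74b, from 4897 ± 686 to 2083 ± 908 TPM. Of 94 nuclear oxidative phosphorylation genes 5 fell (2 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation), and of 54 lysosome genes 10 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.305 with an estimated correlation). Lists of other cell types did not pass camera: adjusted p was 0.421 for superficial keratinocytes, 0.933 for mucous cells, 0.761 for endothelium, 0.837 for fibroblasts and 0.0717 for ionocytes, and basal keratinocytes did not pass either. The mean score of the superficial keratinocyte genes was lower by 0.67 log2 units in mutants (exact permutation test, p = 0.00175, adjusted p = 0.005 over 20 scores), and fry called that list lower (adjusted p = 0.00711). Neither allows for the shift of all genes: the list's median change was -0.25, or 0.03 relative to all genes, and 0.21 with median centring. Within the keratinocyte lists single genes did pass, krt91 rising from 150 ± 141 to 1534 ± 656 TPM and the annexin gene anxa1a falling from 253 ± 103 to 3.92 ± 5.05 TPM (2.04 TPM without mutant epidermis 2).

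The epidermal count was 1367 genes, 39.0% of them higher, without mutant epidermis 2 and 4 and mutant gill 8, the 3 libraries with the fewest detected genes, a choice made after the data were seen. The lysosome call ended in that fit (adjusted p = 0.0852), with a pseudocount of 0.1 (0.0542) and with detected genes as a covariate (0.166), which also ended the oxidative phosphorylation call (0.0505); leaving out 1 library ended the lysosome call in 3 of 14 fits, with a highest adjusted p of 0.0624 without sibling epidermis 1.

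The second comparison put the same question to the gill. Genes of the myeloid list were again lower in mutants. Of 27 neuroendocrine genes 8 rose and 1 fell, a call that the list lost narrowly (adjusted p = 0.0502 with an estimated correlation). There, spi1a fell from 539 ± 169 (SD, n = 5) to 11.7 ± 15.4 TPM (SD, n = 8) and ncf1 from 578 ± 206 to 10.5 ± 6.82 TPM. Without mutant gill 6 the mutant mean of spi1a was 6.36 TPM. The cytokine gene tnfb fell from 204 ± 84.9 to 1.55 ± 1.49 TPM, and il12bb, which encodes an interleukin 12 subunit, from 673 ± 549 to 4.42 ± 5.52 TPM. In mutants sox2 rose from 22.2 ± 29.3 to 347 ± 273 TPM, tph1a, the first enzyme of serotonin synthesis, from 12.6 ± 15.7 to 409 ± 240 TPM, and penka, a precursor of opioid peptides, from 0.580 ± 0.553 to 245 ± 200 TPM. The sibling means were 12.07 TPM for sox2 and 7.99 TPM for tph1a without sibling gill 5, and 0.369 TPM for penka without sibling gill 1.

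Of the 13465 genes, 836 passed in gill, 315 higher and 521 lower, with a median log2 change over all genes of -0.03. The 10 highest named genes rose by 5.76 to 6.75 and were sncgb, tbx1, rgs5a, penka, tspan9b, drgx, gramd2aa, tph1a, smtnl and rasd1. The 10 lowest had log2 changes of -7.27 to -6.05 and were grn2, il12bb, ccr9a, tnfb, il1fma, wasa, gpr132b, il22ra2, nme2b.2 and spi1a. Of these, ccr9a, a chemokine receptor gene, fell from 2584 ± 1301 to 33.1 ± 33.8 TPM. All 20 passed limma at an adjusted p of 0.00127 or lower. Ribosomal protein genes took 11.2 ± 1.67% of TPM in siblings (SD, n = 5) and 5.83 ± 2.41% in mutants (SD, n = 8).

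In gill 10 of the 30 lists passed camera, and 2 held with an estimated correlation. In the leukocyte cytoskeleton list 16 of 22 tested members fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -3.04 and an adjusted p of 0.00117 with an estimated correlation. In the myeloid list 14 of 29 fell and 0 rose (16 and 1 adjusted over the list alone), with a median of -2.76 and an adjusted p of 0.00153 with an estimated correlation. In the neuroendocrine list 8 of 27 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 2.03 and an adjusted p of 0.0502 with an estimated correlation. Its synaptic gene snap25a rose from 3.56 ± 6.39 (0.705 TPM without sibling gill 5) to 102 ± 68.6 TPM. Of 89 ribosomal protein genes 27 fell and 0 rose (70 lower adjusted over the list alone; median -1.11; adjusted p = 0.182 with an estimated correlation), with 41 lower under median centring and 21 under quantile normalization. Of 34 barrier cytokine genes 9 fell and 1 rose (10 and 2 adjusted over the list alone; adjusted p = 0.229 with an estimated correlation). Of 29 ionocyte genes 3 rose and 0 fell (3 adjusted over the list alone; adjusted p = 0.353 with an estimated correlation), and of these atp2b1a rose from 52.5 ± 15.3 to 234 ± 96.8 TPM, while kcnj1a.1 at 235 ± 563 TPM and rhcgb at 313 ± 685 TPM had an SD above their mean in mutants. Without mutant gill 3 the latter means were 37.1 and 79.1 TPM and both calls ended (adjusted p = 0.0839 for kcnj1a.1 and 0.0748 for rhcgb in limma); leaving out 1 library ended them in 8 and 7 of 13 fits. The remaining calls were MHC class II (2 of 15 lower, 4 adjusted over the list alone), neutrophil (2 of 7 lower, 2 adjusted over the list alone), oxidative phosphorylation (3 of 94 lower, 1 adjusted over the list alone) and T and NK cell genes (3 of 10 lower, 4 lower and 1 higher adjusted over the list alone). Their adjusted p values with an estimated correlation were 0.263, 0.182, 0.512 and 0.234. T and NK cell members that fell were ccr9a, cd28 and tagapa. Lists of keratinocytes, mucous cells, endothelium and fibroblasts did not pass in gill, with adjusted p of 0.754 for superficial and 0.276 for basal keratinocytes, 0.614 for mucous cells, 0.781 for endothelium and 0.797 for fibroblasts. The mean score of the basal keratinocyte genes was higher by 0.50 log2 units in mutants (exact permutation test, p = 0.0155, adjusted p = 0.0311 over 20 scores).

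The gill count fell to 552 when gill libraries alone were fitted and to 520 without sibling gill 4. A rank test called 0 genes (2591 at an unadjusted p under 0.05), but its smallest possible p with these numbers of libraries was 0.00155. Many genes would have to reach that value for any to pass, and too few did (smallest adjusted p 0.0824). The rank test therefore does not back the gill calls, and it cannot decide on single genes. In simulated data with 200 changed genes, 16.8% of gill calls were false (median 11 and highest 25 false calls per draw). That share depends on the number of changed genes and need not hold for the real calls. Leaving out 1 library ended the calls for MHC class II, neutrophil, oxidative phosphorylation and T and NK cell genes in 4, 5, 3 and 7 of 13 fits, with highest adjusted p of 0.0755 and 0.0711 (both without sibling gill 2), 0.150 (without sibling gill 1) and 0.0778 (without mutant gill 1); detected genes as a covariate ended the same calls, with adjusted p of 0.0514, 0.0514, 0.0555 and 0.0555.

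**Figure D2:**
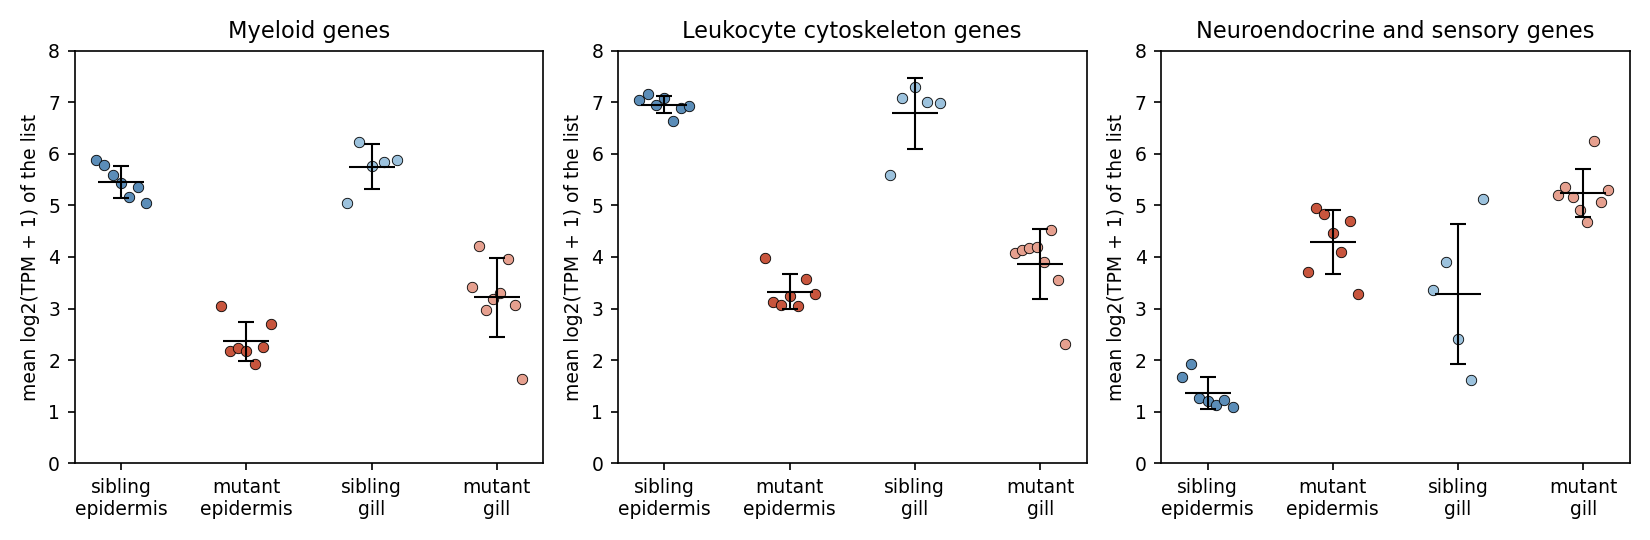
Mean log2(TPM + 1) of the tested members of 3 gene lists on the vertical axis, by group on the horizontal axis; points are libraries, and bars give the mean and SD. The neuroendocrine score was 1.36 ± 0.317 in sibling epidermis, 4.29 ± 0.620 in mutant epidermis, 3.28 ± 1.36 in sibling gill and 5.24 ± 0.464 in mutant gill.

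A further comparison asked whether the mutant effect was alike in both tissues. Across the 13465 genes the log2 changes of the tissues had a Pearson correlation of 0.537 and a Spearman correlation of 0.457, and 64.8% had the same sign. Over 100 labellings with genotypes permuted within tissues, the real one included, the other Pearson values lay between -0.294 and 0.189, so that the permutation p was 0.01, the smallest possible. Genes are not independent replicates, and the contrasts share no library. Of the genes called, 145 were higher in both tissues and 316 were lower in both, the latter against 45.3 for independent lists, while 1 gene was called with opposite signs. Shared lower genes included arpc1b, a subunit of the actin-nucleating Arp2/3 complex, at 1113 ± 365 and 18.3 ± 26.0 TPM (8.59 TPM without mutant epidermis 1) in sibling and mutant epidermis and at 655 ± 284 and 17.3 ± 17.1 TPM in sibling and mutant gill. The iron-storage gene fth1a stood at 14370 ± 2281 and 1239 ± 543 TPM in epidermis and at 8629 ± 3192 and 893 ± 251 TPM in gill.

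**Figure D3:**
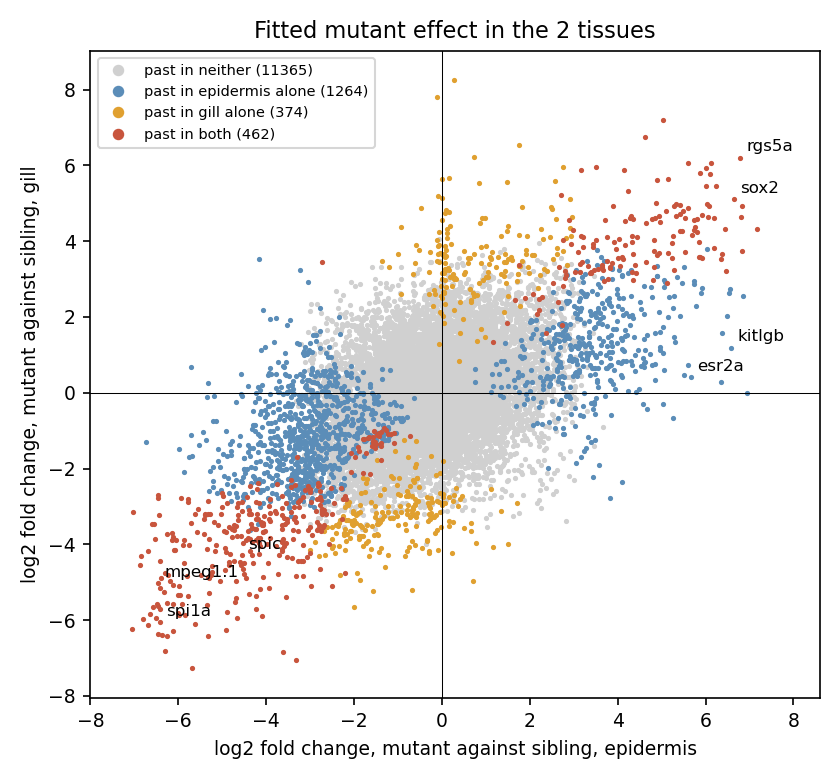
Fitted log2 fold change of each of 13465 genes, mutant against sibling, in epidermis on the horizontal axis and in gill on the vertical axis; colours mark genes past the threshold in both tissues (462), in epidermis alone (1264), in gill alone (374) or in neither (11365). Genes past in both lie mostly at lower left and upper right.

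The difference of the mutant effect between tissues, tested directly as an interaction, passed for 8 genes. The difference, gill minus epidermis, was positive for 5: gpr157, pfkfb3 and cd74b, and the clone-named si:ch211-196h16.12 and si:dkeyp-82a1.4, which were named after their values were seen. It was negative for 3: fosab, socs3a and esr2a. Only si:ch211-196h16.12 passed for mutant against sibling in gill. The others had limma adjusted p of 0.120 to 0.827 there and passed in epidermis. In epidermis gpr157, pfkfb3, cd74b and si:dkeyp-82a1.4 fell (log2 changes -3.92, -3.46, -1.36 and -6.74), while fosab, socs3a and esr2a rose. In mutant gill, gpr157 reached 1 TPM in 3 of 8 libraries. The immediate-early gene fosab differed by -2.88 log2 units (SE 0.49, adjusted p = 0.00819), since sibling gill already held 1626 ± 406 TPM (SD, n = 5) and mutant gill 2838 ± 1438 TPM (SD, n = 8). The glycolytic regulator pfkfb3 stood at 54.2 ± 27.4 and 8.37 ± 12.4 TPM (4.58 TPM without mutant epidermis 7) in sibling and mutant epidermis and at 25.5 ± 7.03 and 105 ± 40.8 TPM in gill (interaction 5.38, SE 0.99, adjusted p = 0.0218). The oestrogen receptor gene esr2a stood at 75.1 ± 44.5 TPM in mutant epidermis, 1.74 ± 4.25 TPM in mutant gill (0.237 TPM without mutant gill 8) and under 1 TPM in all sibling libraries (interaction -5.25, adjusted p = 0.0408). To fill the rule for named genes, cyp1a, ppap2d, spon1b and fgd4b had the next smallest p and missed the threshold. With camera, the difference was negative for immediate-early genes (2 of 54 lower, 12 lower and 2 higher adjusted over the list alone; adjusted p = 0.118 with an estimated correlation), cell cycle genes (0 of 72 past, 0 adjusted over the list alone; 0.520), Notch genes (0 of 23 past, 0 adjusted over the list alone; 0.118) and neuroendocrine genes (0 of 27 past, 0 adjusted over the list alone; 0.520), the bare values being adjusted p with an estimated correlation, so that none held with it. The median interaction over all genes was 0.27, quantile normalization gave 3 higher and 5 lower genes and median centring 1 higher and 6 lower. The count ranged from 2 (without sibling epidermis 3) to 26 (without mutant gill 8) when single libraries were left out, and only fosab and si:ch211-196h16.12 kept the call in every such fit.

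The design also compares the tissues within each genotype. In siblings, the immediate-early and neuroendocrine lists were higher and the basal keratinocyte list was lower in gill than in epidermis. The neuroendocrine score varied widely between sibling gill libraries, from 1.62 to 5.13, against 1.09 to 1.93 in sibling epidermis. The immediate-early gene egr2a stood at 168 ± 75.8 TPM in gill (SD, n = 5) and 4.75 ± 8.68 TPM in epidermis (SD, n = 7; 1.49 TPM without sibling epidermis 7). The keratin gene krt4 stood at 35.9 ± 17.8 TPM in gill and 681 ± 192 TPM in epidermis. The pharyngeal transcription factor gene pax9 stood at 96.3 ± 41.0 TPM in gill and 0.458 ± 0.279 TPM in epidermis. Of the 13465 genes 129 passed, 85 higher and 44 lower in gill; the named ones were s100a11, id3, pax9, egr2a and pvalb8 (higher) and dlx3b, icn2, lmna, ifi46 and lpar6b (lower). Camera called 5 lists. Immediate-early genes were higher (18 of 54, 30 adjusted over the list alone, adjusted p = 0.000231 with an estimated correlation), as were neuroendocrine genes (3 of 27, 8 adjusted over the list alone, adjusted p = 0.0213 with an estimated correlation). The neuroendocrine members atoh1a and insm1b each lost the limma call in most fits that left out 1 library. Their highest adjusted p was 0.159 (without sibling gill 3) and 0.167 (without sibling gill 2). Basal keratinocyte genes were lower (3 of 12, 3 adjusted over the list alone; adjusted p = 0.000231 with an estimated correlation). Superficial keratinocyte genes had 4 of 30 lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.0645 with an estimated correlation), and fibroblast genes 0 of 5 past (2 higher adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). The count fell to 76 without sibling gill 5, to 82 without sibling gill 1 and to 84 without sibling epidermis 6. A rank test called 0 genes (1669 at an unadjusted p under 0.05), but its smallest possible p with these numbers of libraries was 0.00253. Many genes would have to reach that value for any to pass, so the 0 says little about the calls.

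Among mutants, gill and epidermal cells were compared in the same way. The gene epas1b, which encodes a hypoxia-inducible factor, stood at 123 ± 59.1 TPM in gill (SD, n = 8) and 0.376 ± 0.116 TPM in epidermis (SD, n = 7), pax9 at 151 ± 60.4 and 0.894 ± 0.588 TPM, and stc1, which encodes the calcium-regulating hormone stanniocalcin, at 1668 ± 1704 and 34.3 ± 74.8 TPM (6.11 TPM without mutant epidermis 1). Lower in gill was the keratin gene krt91, at 79.4 ± 112 (44.9 TPM without mutant gill 2) and 1534 ± 656 TPM. The other named genes were cyp26b1 and apoeb (higher) and fabp1b.2, icn2, kitlgb and esr2a (lower). In total 569 genes passed, 458 higher and 111 lower, with a median log2 difference over all genes of 0.39; quantile normalization gave 270 higher and 224 lower genes and median centring 148 higher and 241 lower. Camera called 6 lists, of which basal keratinocyte genes held with an estimated correlation (4 of 12 lower, 4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0248). The others lost the call, with adjusted p with an estimated correlation of 0.353 for cell cycle genes (2 of 72 lower, 1 adjusted over the list alone), 0.596 for ribosomal protein genes (4 of 89 higher, 5 adjusted over the list alone), 0.463 for immediate-early genes (11 of 54 higher, 19 higher and 2 lower adjusted over the list alone), 0.582 for mitochondrially encoded genes (1 of 13 lower, 3 adjusted over the list alone) and 0.552 for ionocyte genes (2 of 29 higher, 2 adjusted over the list alone). Fitting the mutant libraries alone gave 119 genes, and detected genes as a covariate gave 214. A rank test called 0 (2317 at an unadjusted p under 0.05), with a smallest possible p of 0.000311.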

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

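The tests of explanations in this part were all chosen only after the results they bear on had been seen. The rule for single libraries and the tests of differences between tissues were fixed before the data were examined.

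Neuroendocrine genes were higher and myeloid genes lower in mutants of both tissues, although in gill the neuroendocrine list lost its call (adjusted p = 0.0502 with an estimated correlation); genotype, the design's biological explanation, may account for it. Fewer cells of the main type, with all other types filling the gate alike, would raise the scores of all other types; the neuroendocrine score rose beyond the mean of 6 others by 3.09 log2 units in epidermis (exact permutation test, p = 0.000583, the smallest possible) and by 1.76 in gill (exact p = 0.00311), where the basal keratinocyte (0.50, adjusted p = 0.0311) and ionocyte scores (1.07, adjusted p = 0.238) also lay higher and the mucous cell score lower (-0.53), so types did not move alike, while added cells of those types stay open. With detected genes in the fit, 93.3% of the called list members stayed past the threshold in epidermis (42 of 45, median size 5.32 before and 4.88 after) while 35.5% of other calls were lost, so detected genes alone do not explain it. In gill 100% of 34 members stayed, but only 7.23% of other calls were lost, so the test cannot decide there. Whether another cell type entered the gate or the same cells changed state was not tested and stays open.

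More genes were lower than higher in mutant epidermis, 1170 against 556, and TPM scaling is a possible cause. The 3366 genes with the highest expression had a median log2 change of -0.59 (-0.69 to -0.47 with single libraries left out) against -0.27 over all genes, which fits a scaling cause. With detected genes in the fit 39.4% of calls were higher, and without mitochondrial features 35.4%, against 32.2% before (30.8% to 35.9% with single libraries left out), so neither of those evens the split. A real loss of abundant transcripts in mutant cells would give the same shift and was not tested apart from it.

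Genes found above 100 TPM in a single library left traces in others, which reads moved between libraries could explain. The mean trace was 0.243% in libraries of other groups with the same replicate number, 0.0142% with another number and 0.221% in the same group (permutation p = 1e-04, the smallest possible for 10000 permutations), which fits moved reads. For 73 genes with under 3% of the sibling level left in mutant epidermis, the residues followed the same-numbered sibling library (mean correlation 0.474, exact permutation p = 0.000198, the smallest possible), which fits as well. Handling of same-numbered samples together, such as cells carried over during sorting, stays open, and no biological explanation was tested. The spic left in mutant epidermis ranged from 1.15% to 19.7% of the sibling mean. Libraries 4 and 6 lay below the highest trace of 1.67%, so moved reads are not excluded as the source of their residue. The other libraries held 3.35% to 19.7%, above that trace. Trace genes were chosen to lie under 5% of their own library's level in all others, so larger traces could not be seen. Sibling epidermis 2, 3 and 7 had 0 such genes, so their traces were not measured. Moved reads would carry other sibling genes too, yet 0.998% of spi1a and 0.799% of ncf1 was left in mutant epidermis. The spi1a and ncf1 values, rather than the trace ceiling, argue against moved reads as the only source of spic in those libraries.

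For 4 of the counts of genes, only 1 of 100 splits of the libraries, the real one, called as many genes. Other splits mix the real groups, which widens the spread and lowers their counts. How many of the real calls arose by chance was therefore not measured. The real and highest other counts were 1726 and 4 for epidermis, 836 and 94 for gill, 129 and 9 for tissues in siblings and 569 and 17 for tissues in mutants. For the interaction the real split was also the only 1 of 100, but its 8 genes stood close to the highest other count of 5.

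Single libraries lay far from the others of their group in 30 of 179 groups of values tested. The range of the others is in brackets. Chance gives about 1 in 20 for normally distributed values, but some of the values tested lay near the floor. There about 1 read can stand apart, as for fgd4b in mutant epidermis 3, where 1 read was worth a median of 0.17 TPM. The count of 30 is therefore not set against chance. In sibling epidermis 1 these were chga 12.4 TPM (0.5004 to 2.28), kitlgb 51.3 TPM (0.314 to 2.63), spon1b 3.95 TPM (0 to 0.231), icn2 78.6 TPM (284 to 530) and lmna 21.5 TPM (39.3 to 53.3). In sibling epidermis 2 they were cd74b 6335 TPM (4416 to 5034) and the share of the most abundant feature, 11% (17.2% to 19.5%). Sibling epidermis 5 stood apart in id3, 44.3 TPM (0 to 2.75), and sibling epidermis 7 in egr2a, 24.3 TPM (0.375 to 3.34). Mutant epidermis 7 was the lowest library for scgn, 284 TPM (2103 to 4756), fxyd6, 6.76 TPM (146 to 828), rgs5a, 185 TPM (1292 to 4627), insm1b, 5.65 TPM (173 to 685), yjefn3, 2.08 TPM (79.5 to 343), esr2a, 4.49 TPM (38.2 to 142), and krt91, 399 TPM (1226 to 2379). Mutant epidermis 1 stood apart in gpr157, 0.4998 TPM (0 to 0.189), and mutant epidermis 3 in fgd4b, 0.195 TPM (others 0).

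Sibling gill 1 was far from the others in mpeg1.1, 12.2 TPM (113 to 140), ccr9a, 520 TPM (2404 to 4027), gpr132b, 42.5 TPM (190 to 278), and cyp1a, 42.5 TPM (0.218 to 1.77). Sibling gill 2 was so in rasd1, 306 TPM (5.71 to 10.24), pax9, 31.3 TPM (92.1 to 136), and lpar6b, 61.4 TPM (0.237 to 1.3997), and sibling gill 3 in tbx1, 1.36 TPM (0.115 to 0.184). Mutant gill 3 had 13.6% mitochondrial mRNA (4.60% to 7.98%) and fgd4b at 0.297 TPM (others 0), and mutant gill 8 had gramd2aa at 1.48 TPM (49.2 to 524) and esr2a at 12.2 TPM (0 to 0.498). The whole profile of mutant gill 8 stood apart: it lay at 235 on the principal component that holds 5.23% of the variance (all others -36.3 to 25.05) and had 9951 genes above 0 (13486 to 16159 in the rest of its group).

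The mutant effect differed between gill and epidermis, tested in limma, for 8 genes: gpr157 by 5.86 log2 units, si:ch211-196h16.12 by 5.50, si:dkeyp-82a1.4 by 5.43, pfkfb3 by 5.38, cd74b by 1.72, fosab by -2.88, socs3a by -3.50 and esr2a by -5.25. For lists it differed with camera for cell cycle (median -0.47), immediate-early (-0.97), neuroendocrine (-0.92) and Notch genes (-1.25), none of them with an estimated correlation.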

How the results depend on the processing

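The fits without mitochondrial features, with values under 1% of a gene's highest library set to 0, without the 3 libraries with the fewest detected genes, with the ribosomal list without kinases, and leave-one-out tests of lists and of means of the genes printed were chosen after the results were seen; all other alternatives were fixed before the data were examined. All 40 named genes of the mutant contrasts kept direction and threshold under both scalings, the covariate, array weights, the block and every leave-one-out fit. The epidermal count stayed within 1.5 times of 1726 throughout (rank test 1372; 1473 to 1736 with single libraries left out). Where a count moved further, the cause was not tested. The gill count of 836 became 552 in a fit of gill libraries alone and 0 in the rank test. The smallest adjusted p of that test was 0.0824, and its smallest possible unadjusted p was 0.00155. With single libraries left out the gill count ranged from 520 (without sibling gill 4) to 884. The 8 interaction genes became 26 with a pseudocount of 0.1, 13 with a pseudocount of 10, 13 without a filter, 19 with array weights and 3 with the covariate. Leaving out libraries gave 2 to 26: fewer than 6 without sibling epidermis 1 to 5, mutant epidermis 2 to 4, sibling gill 1 or 3, or mutant gill 4, and more than 13 without sibling gill 2, mutant gill 1, 7 or 8, or mutant epidermis 1 or 7. The 129 tissue genes in siblings became 72 with the stricter filter, 245 with array weights and 0 in the rank test (smallest possible p 0.00253). They ranged from 76 to 119 (76, 82 and 84 without sibling gill 5, sibling gill 1 and sibling epidermis 6). The 569 in mutants became 358 without a filter, 360 with array weights, 119 in a fit of mutants alone, 214 with the covariate and 0 in the rank test, and ranged from 406 to 643.

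The 11 lists in epidermis became 17 with a pseudocount of 10, 5 with an estimated correlation and 20 with fry (10 to 15 leave-one-out), and the 10 in gill became 6 with the covariate and 2 with an estimated correlation (7 to 11 leave-one-out). With single libraries left out the log2 change of spic ranged from -4.92 to -4.27 in epidermis and from -4.56 to -4.02 in gill; a pseudocount of 10 gave -4.05 and -3.49. The correlation between tissues was 0.486 and 0.591 with pseudocounts of 0.1 and 10 and 0.544 with quantile normalization.

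With the replicate block, epidermis gave 1828 genes, gill 870, the interaction 18, siblings 100 and mutants 695, with 11 and 7 lists (in gill neutrophil, oxidative phosphorylation and T and NK cell genes did not pass, at adjusted p of 0.0649, 0.0624 and 0.0624); spic changed by -3.81 in gill over 5 pairs (exact permutation p = 0.0625, the smallest possible). Same-numbered libraries correlated by -0.0308 to 0.0776 once group means were removed, none above 0.1. In 3 of the 6 pairs of groups each of 7 libraries matched its own number best. In the pairs with sibling gill 2 or 3 of 5 did. The tie was small in size but regular among the other groups, and the traces between libraries also followed the number. The main fit leaves this tie out, while the replicate block takes it in.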

Other observations

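No hypothesis was tested in this part; the genes below were chosen after their values were seen, and no tests beyond limma and camera were made.

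Single genes of ion channels and vesicle fusion passed limma in both tissues; no list of such genes was tested. The potassium channel gene kcnd2 stood at 1.76 ± 2.81 TPM (SD, n = 7; 0.701 TPM without sibling epidermis 1) in sibling and 148 ± 110 TPM (SD, n = 7) in mutant epidermis, and at 7.96 ± 6.72 TPM (SD, n = 5) and 127 ± 75.9 TPM (SD, n = 8) in gill. The potassium channel gene kcnh6a stood at 52.3 ± 30.8 and 338 ± 140 TPM in epidermis and at 28.0 ± 17.3 and 149 ± 80.9 TPM in gill. The vesicle fusion gene stxbp1a stood at 0.517 ± 0.312 and 91.4 ± 76.1 TPM in epidermis and at 3.74 ± 6.09 (1.05 TPM without sibling gill 5) and 129 ± 105 TPM in gill. The calcium-activated potassium channel gene kcnma1a stood at 0.719 ± 0.684 and 38.9 ± 22.4 TPM in epidermis and at 0.671 ± 0.575 and 32.6 ± 30.3 TPM in gill.

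The iron and heme list did not pass camera (adjusted p = 0.0642 in epidermis and 0.0947 in gill), with 4 of 20 members lower in epidermis and 3 lower and 2 higher in gill. Its transferrin receptor gene tfr1b stood at 516 ± 140 TPM in sibling and 65.2 ± 46.9 TPM in mutant epidermis (SD, n = 7 each), and at 298 ± 143 TPM (SD, n = 5) and 20.1 ± 21.1 TPM (SD, n = 8) in gill, with limma adjusted p of 0.000499 and 4.25e-05.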
